A study of Mus musculus with 2 samples.

How the data were processed

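Total RNA from C2C12 myotubes was profiled on an expression array in 2 samples, 1 of control myotubes and 1 of myotubes treated with 100 µM hydrogen peroxide, both at day 5 after differentiation. C2C12 is an immortalised mouse muscle cell line whose myoblasts fuse into myotubes when they differentiate. The duration of the exposure, the type of array and the number of cultures behind each sample are not given in the sources used here.

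The deposited table holds 1 value per feature and sample for 149 features. The values were taken as intensities, the brightness of an array feature on a linear scale, because the deposited values are whole numbers that are either exactly 0 or lie between 7053 and 54816. How the authors scanned, background-corrected, scaled or filtered these deposited intensities is not given in the sources used here. The lowest value above 0 was 7150 in the control sample and 7053 in the treated sample, and no value in either sample lay between 0 and these. A value of 0 is therefore read as a value under a limit or a rejected spot, not as a measured level. All 41 control values above 0 were even numbers, whereas 10 of the 22 treated values were even and 12 were odd, and whether the columns were recorded on the same scale is not given in the sources used here. No scanner output was used here.

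The features carry only an ID, a letter M or T with a number, and the table does not pair the IDs with genes. None of the 149 IDs is an accession or a locus tag in the mouse RefSeq gene table used for names. A current symbol or synonym in that table coincides with 6 of the IDs, and 1 of these coincides with names of more than 1 gene, so no gene name was taken from such matches. The 17 gene lists fixed before the data were examined (stress, redox, chaperone, apoptosis, inflammation, muscle and reference genes among them) therefore could not be applied, no list result is given, and features are described by ID or as a group.

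A feature counted as measured when its value exceeded the lower quartile of its column, which was 0 in both columns. For the features measured in both samples, the log2 ratio of treated over control was computed from the deposited intensities and centred on the median log2 ratio of those features. Features were counted as higher or lower at a fold of at least 2. A feature at 0 in one sample was given as listed at 0, with no fold. The rule fixed beforehand named the features with the largest change in each direction, and, because the features have no gene names, at most 2 that were higher and 2 that were lower by ID. The reference features and blanks that the rule also covers could not be identified from the IDs.

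With 1 sample per group there was no replicate, so no test between the conditions was run, no p-value or SD over samples is given, and the precision is limited by the number of arrays. The SD quoted is over features within this single pair of arrays. The calculation was tested on simulated data made from the 22 features measured in both samples. It recovered 6 of 6 features changed by a fold of 4, with a largest error of 0.20 on the log2 scale. The simulated scatter was smaller than that of the data, where the SD of the log2 ratios was 0.56. The simulation therefore checks the arithmetic and does not measure the accuracy of the real comparison. Alternatives covered the scaling of the columns, the floor, the pseudocount and the fold threshold. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.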

Results

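The series compared C2C12 myotubes, the multinucleate muscle cells that a mouse myoblast line forms in culture, with and without exposure to 100 µM hydrogen peroxide, an oxidant, at day 5 after differentiation. A single array was deposited for each condition, so every difference below is between 2 samples with no replicate check. The deposited data held 149 features, of which 58 had an ID starting with M and 91 an ID starting with T. The intensities summed to 703246 in the control sample and to 475188 in the treated sample.

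On the values as deposited, fewer features were listed above 0 in the myotubes treated with hydrogen peroxide. In the control sample 41 of the 149 features (27.5%) were listed above 0, against 22 (14.8%) in the treated sample. All 22 features listed in the treated sample were also listed in the control sample, 19 were listed in the control sample only, none was listed in the treated sample only, and 108 were at 0 in both. The 19 features had control intensities from 7150 to 28794 with a median of 10516, and together they held 230770 of the control sample's total, or 32.8%. Of these 19 features, 6 had a control intensity of at least 14106, which is 2 times the lowest treated value above 0, and the other 13 were closer to that lowest value. The 22 features listed in both samples summed to 472476 in the control sample and to 475188 in the treated sample, so the lower total of the treated sample lay in the features listed at 0 there. The control values above 0 were all even numbers, and a change in their scale alone leaves the number of features above 0 as it is. With the control values halved and, in addition, the lowest treated value of 7053 set as the limit in both samples, 18 control features reached it against 22 treated ones. The treated count is fixed by this choice of limit, so the 2 counts show only how the comparison depends on scale and limit.

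The features listed in the control sample only were spread over both ID series. Among the 91 features with an ID starting with T, 18 were listed in the control sample and 7 in the treated sample, which left 11 in the control sample only. Among the 49 features with an ID starting with M but not with M90, 14 were listed in the control sample and 6 in the treated sample, which left 8 in the control sample only. All 9 features with an ID starting with M90 were listed in both samples. That last group was singled out after its values were seen, and the labels do not say what it is.

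Most features listed in both samples had similar intensities with and without hydrogen peroxide. This set leaves out the 19 features at 0 in the treated sample, which favours similar values. Among features with a control intensity of at least 14106, the 12 listed in both samples had a median deposited log2 ratio of -0.04. All 18 such features had one of -0.38 with the other 6 set at the lowest treated value. The median ratio of treated over control was 0.98 as deposited, and after centring on it 18 of the 22 features lay within 1.5-fold of no difference. The SD of the centred log2 ratios over the 22 features was 0.56, with quartiles at -0.13 and 0.26. Across these features the log2 intensities of the 2 samples had a Pearson correlation of 0.84 and a Spearman correlation of 0.86. Features are not independent replicates, and these values describe this pair of arrays only. Since 12 of the 22 treated intensities were odd numbers and no control intensity was, the scaling of the columns to each other before deposit is uncertain.

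Among the 22 features with a ratio, 1 was at least 2-fold higher in the treated sample and 2 were at least 2-fold lower. The 19 features at 0 in the treated sample have no ratio and are not counted here. Of these 19 features, 6 had a control intensity of at least 2 times the lowest treated value above 0. These counts were 2 higher and 0 lower with equal column totals, and 8 higher and 0 lower after quantile normalization. Both scalings take in the values listed at 0, which are not read as measured levels. Feature T9 had an intensity of 17048 in the control sample and 34210 in the treated sample, a centred log2 ratio of 1.03. This ratio lay close to the 2-fold threshold, and it was 0.79 when centred on the M90 features, 1.57 with equal column totals and 1.31 after quantile normalization. The next highest, M758, went from 7344 to 10751, a log2 ratio of 0.58 that did not reach 2-fold. The M758 ratio was 0.33 when centred on the M90 features, 1.12 with equal column totals and 1.93 after quantile normalization. Its control value lay near 7150, the lowest control value above 0. Feature M511 had an intensity of 32908 in the control sample and 11231 in the treated sample, a log2 ratio of -1.52, and T29 had 20174 and 7675, a log2 ratio of -1.37. Both were under 2-fold when the columns were scaled to equal totals, at -0.99 and -0.83, and after quantile normalization, at -0.90 and -0.72. Centred on the M90 features, they were at -1.77 and -1.61. The treated value of T29 lay near 7053, the lowest treated value above 0. Without replicates, none of the 4 differences can be set against the variation between samples of one condition.

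**Figure D1:**
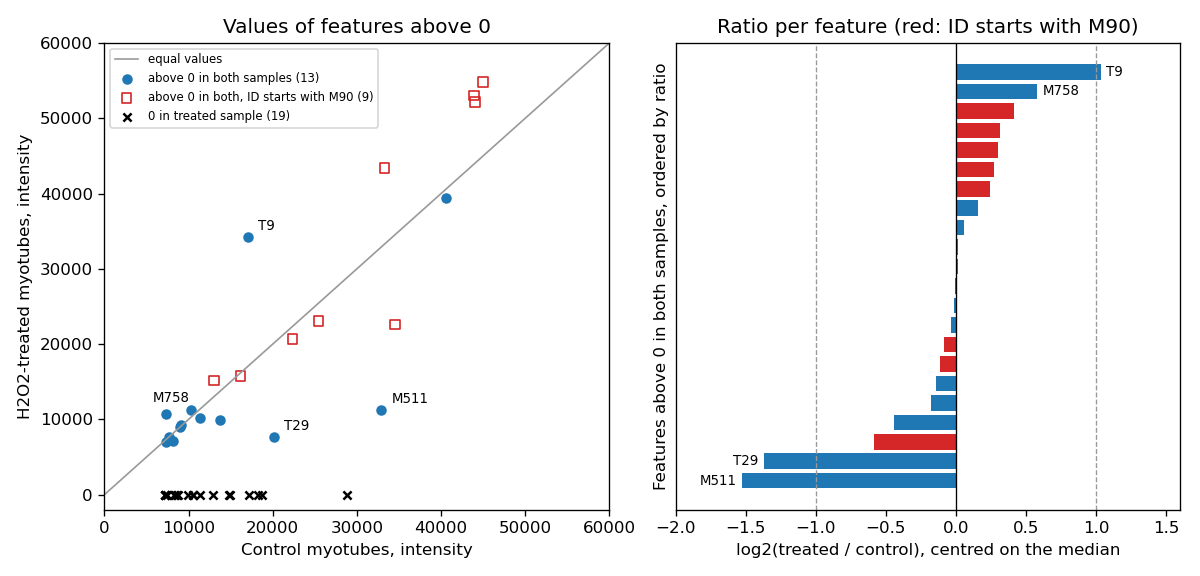
Left, intensity (linear axes) of each feature above 0 in the control sample (x axis) and in the treated sample (y axis), with the line of equal values; the 19 crosses at the bottom are features at 0 in the treated sample, and squares are features with an ID starting with M90. Right, log2 ratio of treated over control for the 22 features above 0 in both samples, centred on their median, with dashed lines at 2-fold; T9 lies beyond the upper line at 1.03, and T29 and M511 lie beyond the lower line at -1.37 and -1.52.

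The 9 M90 features had intensities from 13036 to 44978 in the control sample and from 15142 to 54816 in the treated sample. Their sum was 277680 in the control sample and 300564 in the treated sample, a ratio of 1.08. Centred log2 ratios in this group ran from -0.59 to 0.41 with a median of 0.24, and 5 of the 9 features were above 0. The remaining 140 features summed to 425566 in the control sample and to 174624 in the treated sample. Of that control sum, 230770 lay in the 19 features listed at 0 in the treated sample. Since a 0 is not read as a measured level, the fall in this sum is not a measured ratio. It cannot be set against that of the M90 features, all of which were listed in both samples.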

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

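A common floor, centring on the M90 features and halving the control values with a new floor were chosen after seeing the data; the other settings were planned. The counts of 1 feature at least 2-fold higher and 2 lower were unchanged on the values as deposited, without a floor, with the column median as the floor and with the lower quartile as a pseudocount (the last 3 moved nothing, since both quartiles and medians are 0). The counts became 2 higher and 0 lower with equal column totals, and 8 higher and 0 lower with quantile normalization, both of which take in the values listed at 0. They became 0 and 0 at a 3-fold threshold, and 1 and 3 at a 1.5-fold threshold. Centring on the M90 features left 0 higher and 2 lower. Halving the control values together with a floor at the lowest treated value kept the counts at 1 and 2, with 6 features in the control sample only, 10 in the treated sample only and 12 in both. Centring on the median removes a uniform change of scale, so only the choice of features by the new floor could move these fold counts. A common floor of 10000 gave 0 higher and 1 lower, and one of 15000 gave 0 and 0, with fewer features left and another median. The split of 19 features above the floor in the control sample only, 0 in the treated sample only and 22 in both became 12, 1 and 14 with the floor of 10000, and 6, 1 and 10 with that of 15000. No log2 ratio of the 4 features given by ID changed sign in any setting that gave one. The floor of 10000 left M758 and T29 without a ratio, and that of 15000 left only T9 with one. Halving the control values with the new floor left M758 without one. Centring on reference features and every setting of the gene lists were not run because no feature could be named. No paired analysis was possible because each condition has 1 sample. Intensities under about 7053 on the treated array are not listed, so differences below that level cannot be seen.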

Other observations

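All tests in this part were chosen after the values were seen. Of the 19 features listed in 1 sample only, 0 were in the treated sample, a share of at most 17.6% by its exact 95% interval. This argues against scatter around a shared limit as the whole cause, since that would give about 50%. The argument holds only if features are independent and if the deposited values share 1 scale and limit. Halved control values together with a floor at the lowest treated value give 10 features in the treated sample only and 6 in the control sample only. A change of scale alone, without the new floor, leaves the split as it is. Bringing the brightest of the 19 to the lowest treated value takes a uniform log2 ratio of -2.03. For a higher background subtracted on the treated array, it takes a uniform intensity difference of -21741. The 7 features brighter than all 19 in the control sample had a median log2 ratio of 0.24 (from -1.55 to 0.38). Their median intensity difference, treated minus control, was 8143 (from -21677 to 10130). These values argue against either, acting alone and evenly on every feature, as the cause of the whole pattern. The lowest difference, that of M511, nevertheless came close to the one needed. Outside the M90 group these 7 held only T24, at -0.04, and M511, at -1.55. Both medians therefore rest mainly on the M90 group, which was singled out after its values were seen. The ratio and the difference needed are also set by 1 feature, M229, at 28794 in the control sample. The next brightest of the 19, T68, was at 18676. A uniform change combined with scatter between the arrays was not tested, and it stays open for the brighter features of the 19 too. For the dimmer features of the 19 a smaller uniform fall, of -0.58 for the median one, stays open. Of the 18 features with a control intensity of at least 14106, the 12 listed in both samples had a median log2 ratio of -0.04. Most of these 12 were M90 features. All 18 had a median of -0.38 with the other 6 set at the lowest treated value. Their lower quartile was then -1.35, below the -0.58 needed, so these values cannot exclude such a fall. A smaller rise in the background subtracted on the treated array stays open for the dimmer features of the 19 too. It cannot be excluded by the 7 features kept although no brighter in the control sample than the median of the 19. By construction, those 7 are the ones that stayed above 0. A value of 0 can also be a rejected spot, and rejection of spots on the treated array was not tested. A change in these transcripts with hydrogen peroxide is an untested explanation. With 1 array per condition it cannot be separated from rejected spots or from what stays open.

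Every one of the 41 control values above 0 is even, while 12 of the 22 treated values are odd. Candidate explanations, which the even numbers prompted and so do not test, are that the control values were doubled before deposit, or recorded in steps of 2, which would leave their scale as it is. As deposited, the lowest values above 0 lie close together at 7150 and 7053 and the median ratio of the 22 shared features is 0.98, whereas halved control values would start at 3575. These values do not settle whether a doubling took place, since one made to bring the arrays to a common scale would leave the same agreement. With the control values halved and the lowest treated value as the floor, 10 features reach it in the treated sample only and 6 in the control sample only, against 0 and 19 as deposited. All 22 treated features reach that floor by construction, so this split cannot show whether a doubling took place. No biological explanation was tested.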
